A study of Mus musculus with 6 samples.

How the data were processed

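Poly(A) RNA was sequenced from mouse bone marrow cells sorted as long-term repopulating hematopoietic stem cells, the rare cells that can rebuild blood after transplantation. Per the labels, C57BL mice received the vehicle DMSO or the small molecule YH250, described by the submitters as an antagonist of the interaction between the coactivator p300 and catenin, at 2 mg per kg under the skin. Bone marrow was taken 16 h later and sorted for cells lacking lineage markers and carrying Sca1 and c-Kit, with CD41 and CD48 absent and CD150 present. Per the labels' protocols, cDNA was made with an ultra-low-input full-length kit, sonicated and sequenced as single-end reads. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.8, Partek and the mouse build mm10, without saying which did what, and the gene annotation behind the deposited IDs is not given in the sources used here.

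The deposited file holds 1 normalized signal per gene and library for 41128 Ensembl mouse genes, made by the authors from reads assigned to genes. Its unit is not stated and was worked out from the values. The lowest value in every column is exactly 1, and the excess over 1 falls on multiples of the same small step for genes of any length, so the values were read as RPM (reads scaled to one common total per library) plus an offset of 1. The step gives what 1 read was worth, 0.0321 to 0.0455 RPM, and hence 21.96 to 31.19 reads at 1 RPM. Between 60.1% and 67.6% of the low values (up to 20 reads) lay within 0.1 of a whole read; the rest were fractions, as sharing of reads between genes would give, so whole reads were not recovered and no count model was used. After subtraction of the offset the genes of a library summed to 699979 to 959240 RPM, that is 70.0% to 95.9% of the total to which a library was scaled. Reads from near-identical copies (heat shock genes Hspa1a and Hspa1b, histone, globin and ribosomal protein genes) could be split by such sharing, and it is not stated whether strand was used, so antisense and overlapping genes such as Kcnq1ot1 are uncertain.

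Gene symbols were matched on the Ensembl ID without version for 40254 of the 41128 genes, and positions are from GENCODE M21 on GRCm38, the assembly also called mm10. The offset was removed, 13597 genes with a mean of at least 1 RPM over all 6 libraries were kept, and log2(RPM + 1) was tested, so the pseudocount of 1 equals the authors' offset. A fold change on this scale understates the change of low genes. YH250 minus DMSO was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), 3 against 3 libraries, with Benjamini-Hochberg adjustment over all tested genes at 0.05. A total of 32 gene lists (blood cell identity and division mode, Wnt signalling, cell cycle, stress, immune response, metabolism, chromatin, the sort markers, and markers of other bone marrow cells) were fixed before the data were examined, as were the test, the rule for naming genes and the alternatives, except those described as chosen after the data had been seen. No list was chosen on these samples. They were tested with limma's camera, which compares a list with all other tested genes, two-sided, with the preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. By the rule, the text names the 12 genes of largest change in each direction among those that pass and whose groups do not overlap, filled up to 12 with the genes of smallest unadjusted p where fewer pass, passing over unnamed gene models. It also takes the 4 leading members of each list that passes, the 2 leading members of other lists, and 17 genes fixed in advance. All are tabulated and those of interest for each comparison are given here, except that some genes the rule takes are not reported here.

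The labels number the libraries of each group 1 to 3. Whether these numbers pair the libraries was checked by the correlation of each library's deviations from its group mean over the tested genes. Libraries of the same number correlated at 0.55, 0.26 and 0.70 for numbers 1, 2 and 3. All 3 values were above 0.1, the limit for treating the numbers as pairs, and in these deviations each library correlated best with the library of its own number. A fit with the number as a block is therefore given wherever it changes a result. DMSO 2 with YH250 1 (0.144) and DMSO 1 with YH250 2 (0.109) also exceeded the limit, so the pairing of number 2 is the least secure. On the log2 values themselves DMSO 2 correlated more with YH250 1 (0.947) than with YH250 2 (0.903). In the deposited column names the letter F stands before each number, and its meaning is not given. The labels do not say what a number stands for, nor that the libraries came from separate animals. The p-values therefore measure only the spread between these libraries. Contrasts between numbers were chosen after the data had been seen and were fitted with treatment as a second term, 2 libraries per number.

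The scripts were tested on simulated data, with counts drawn for the 13597 tested genes from each number's means and each library's depth, and 200 genes changed. At a dispersion of 0.05 and a 4-fold change, 31% of the changed genes were recovered without the block and 100% with it; at a 2-fold change, 0% and 52%. At a dispersion of 0.2 and a 4-fold change, 0% were recovered without the block and 45% with it, and at a 2-fold change 0% with either fit. A shift of 0.5 on the log2 scale in the interferon list alone gave camera adjusted p-values of 0.00538 or smaller in all 4 settings, and no other list was called. The simulated genes were drawn independently of each other, so this cannot show how often camera calls lists whose genes vary together. With the block, 7 to 20 unchanged genes were also called in the settings that recovered any. Alternatives covered the pseudocount, the minimum mean, 2 other scalings, limma's options, array weights, the block, leaving out libraries, other list tests, and a correction for transcript length and GC content. Of these, the removal of both libraries of a number and the length and GC correction were added after the data had been seen. So were the estimated correlation and limma's fry test under the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.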

Results

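The series compared the transcriptomes of sorted long-term repopulating hematopoietic stem cells from mice given YH250 with those from mice given DMSO. According to the submitters' design note, genes acting in stem cell maintenance and symmetric expansion were anticipated to be higher after YH250. There were 3 libraries per group, numbered 1 to 3 in each. The low values put the worth of 1 read at 0.0384, 0.0368 and 0.0455 RPM (reads scaled to one common total per library) in DMSO 1, 2 and 3, and at 0.0321, 0.03997 and 0.0417 RPM in YH250 1, 2 and 3, so a gene at 1 RPM rests on about 21.96 to 31.19 reads. Between 12716 and 13459 genes reached 1 RPM in a library. Mitochondrial transcripts took 5.07% to 6.32% of the reads in genes, and the 10 most abundant genes took 6.88% to 10.9%.

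The transcripts of Slamf1, Cd48, Flt3 and Mecom differed more between replicate numbers than between treatments, whereas the log2 difference of the sort marker Kit was -0.66 between treatments and -0.66 between numbers 3 and 1. Slamf1, which encodes CD150 (chromosome 1, 171767127 to 171801184), stood at 35.5 RPM in DMSO 1 and 31.5 RPM in YH250 1, but at 0.515 and 3.92 RPM in the libraries numbered 2 and at 4.69 and 1.54 RPM in those numbered 3. Cd48, which the sort was to exclude (chromosome 1, 171682009 to 171705258), was at 10.2 and 13.1 RPM in number 1, 31.5 and 66.9 RPM in number 2, and 258 and 252 RPM in number 3. Itga2b, which encodes the likewise excluded CD41, went the other way, with 43.7 and 37.4 RPM in number 1 and 5.65 and 7.13 RPM in number 3. Ly6a, which encodes the required Sca1, was at 80.9 and 122 RPM in number 1 and at 241 and 319 RPM in number 3. Flt3, a receptor of multipotent and lymphoid-primed progenitors, was at 26.6 and 28.9 RPM in number 1 and between 224 and 271 RPM in the other 4 libraries. Mecom, a transcription factor of stem cells, was at 116 and 92.1 RPM in number 1 and at 28.8 and 22.7 RPM in number 3. With limma, 1164 genes differed between numbers 3 and 1 at an adjusted p under 0.05 (761 higher and 403 lower in number 3), 858 between numbers 3 and 2, and 27 between numbers 2 and 1. All 6 libraries carry the same submitters' description of the sorted population, and transcript levels need not follow surface protein.

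**Figure D1:**
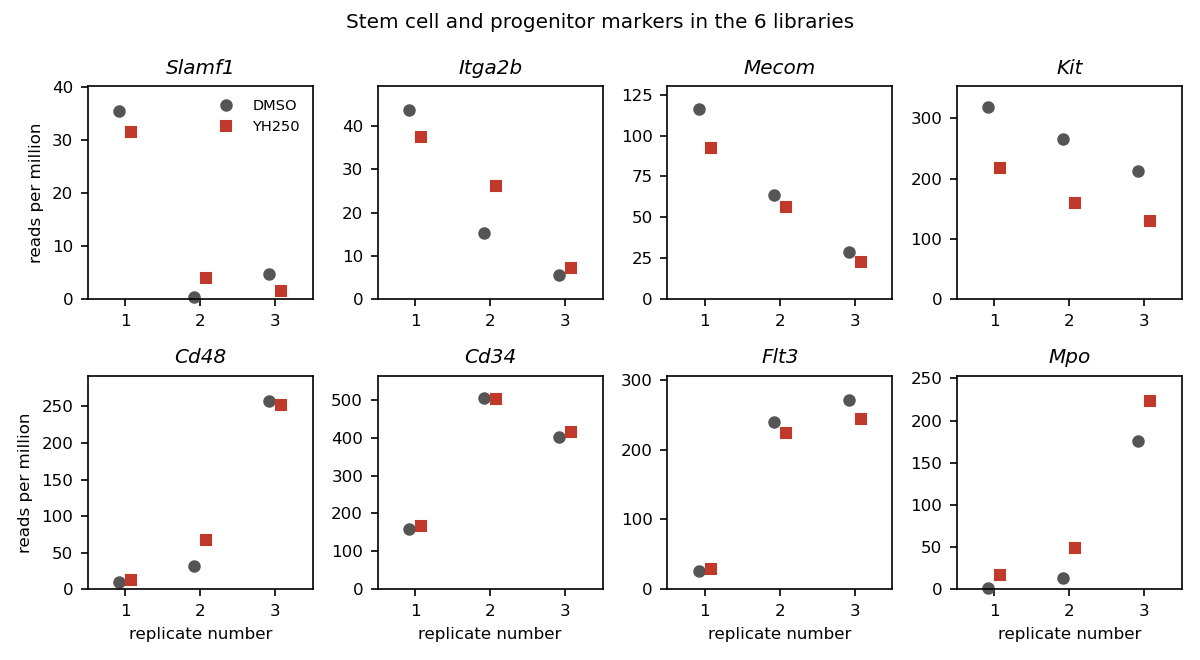
Expression in RPM (vertical axes, from 0) of 8 stem cell and progenitor genes in each library, by replicate number (horizontal axes), with DMSO as grey circles and YH250 as red squares, 1 point per library. Cd48 lies at 258 and 252 RPM in the libraries numbered 3 against 10.2 and 13.1 RPM in those numbered 1, while Kit lies lower in YH250 than in DMSO at each number.

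No gene differed between YH250 and DMSO at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 13597 genes). The smallest adjusted p was 0.999 without the replicate block and 0.66 with it. At an unadjusted p under 0.05, limma gave 231 genes without the block and 1012 with it; libraries without any structure by number or treatment would give about 680. The median log2 fold change over all genes was 0.02, and the median standard error of a gene's log2 fold change was 0.39 without and 0.30 with the block.

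Among the genes of smallest unadjusted p, none of which passed, those with higher means in YH250 included the following. Tcf19 had 8.55 ± 3.52 RPM in DMSO and 26.7 ± 9.22 RPM in YH250 (SD, n = 3 each, as for all pairs of values that follow), and the DNA ligase Lig1 had 59.7 ± 6.93 and 101 ± 10.5 RPM. The replicative polymerase subunit Pole had 26.4 ± 3.02 and 48.9 ± 9.21 RPM, the mitotic kinesin Kif2c 8.14 ± 1.24 and 19.0 ± 3.41 RPM, and Gtse1, expressed in G2 and S phase, 3.35 ± 4.03 and 15.6 ± 3.65 RPM. The mitochondrial import gene Timm50 had 45.0 ± 5.77 and 81.0 ± 13.6 RPM. Hist2h3b, a histone gene with near-identical copies, and the zinc finger gene Zfp317 had log2 differences of 1.91 ± 0.50 and 1.66 ± 0.47 (SE). Genes with lower means in YH250 included Rictor, a subunit of the TORC2 kinase complex (52.3 ± 1.72 and 28.8 ± 6.42 RPM), the SRC-family kinase Yes1 (14.4 ± 4.06 and 5.09 ± 1.799 RPM), the DNA ligase Lig4 (4.57 ± 0.968 and 0.948 ± 0.623 RPM) and Errfi1, a feedback inhibitor of EGF receptor signalling (2.75 ± 1.16 and 0.197 ± 0.128 RPM). Gprasp1, Mid1 and Mbtps2 had log2 differences of -1.10, -1.40 and -1.19, and Jrk had 6.86 ± 4.13 and 1.29 ± 1.084 RPM. The long noncoding RNAs Xist (372 ± 22.9 and 241 ± 30.8 RPM) and Kcnq1ot1 (426 ± 121 and 240 ± 49.1 RPM) were also lower in mean. For each gene named in this paragraph the sign of the difference was the same at all 3 replicate numbers. The genes were chosen by their p in these same libraries, which favours a shared sign, so this is no separate evidence.

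Genes of cholesterol synthesis fell as a group after YH250. Of 22 members tested, 18 had lower means and 10 were lower at all 3 replicate numbers, and the list's median log2 fold change was -0.36 (camera adjusted p = 1.3e-05; adjusted p = 0.247 with an estimated correlation). Cyp51, a sterol demethylase (chromosome 5, 4081145 to 4104746), had 42.5 ± 5.20 RPM in DMSO and 24.0 ± 4.89 RPM in YH250, Hmgcs1, which makes the HMG-CoA used for cholesterol, 44.2 ± 12.6 and 24.2 ± 6.56 RPM, and Sqle, which oxidizes squalene, 36.5 ± 3.09 and 22.9 ± 6.08 RPM. Mbtps2, a protease that activates sterol-responsive transcription factors and is not a member of the list, had 31.0 ± 9.27 and 13.2 ± 4.25 RPM. Over all genes 0 of the 22 members passed with limma (6 had an unadjusted p under 0.05), and adjusted over the list alone 0 passed without the block and 4 with it.

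Interferon-stimulated genes rose as a group, with a median log2 fold change of 0.37 over 39 members (camera adjusted p = 1.3e-05; adjusted p = 0.247 with an estimated correlation). In mean, 32 members were higher, and 22 were higher at all 3 replicate numbers. Usp18, which restrains interferon receptor signalling (chromosome 6, 121245906 to 121270917), had 13.8 ± 1.61 RPM in DMSO and 37.4 ± 19.4 RPM in YH250. The transcription factor Irf7 had 14.0 ± 7.55 and 39.0 ± 23.9 RPM, the nucleotide kinase Cmpk2 11.8 ± 3.45 and 29.4 ± 17.4 RPM, and the exonuclease Isg20 23.9 ± 3.05 and 35.5 ± 2.05 RPM. The highest values of Usp18, Irf7 and Cmpk2 were those of YH250 2 (59.7, 65.8 and 49.4 RPM), a library that stood apart on the second principal component of all tested genes (-79.3, against -0.846 to 36.2 in the other 5). It also had the highest levels of the stromal gene Lepr (58.2 RPM, against 0.0455 to 7.99) and of the endothelial gene Plvap (44.97 RPM, against 1.27 to 10.7). Without YH250 2 the interferon list's median was 0.31 (camera adjusted p = 2.7e-05). Over all genes 0 members passed with limma (3 had an unadjusted p under 0.05), and adjusted over the list alone 0 passed without the block and 4 with it.

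Heat shock genes rose as a group as well, with a median log2 fold change of 0.21 over 19 members (camera adjusted p = 0.00447; adjusted p = 0.247 with an estimated correlation). In mean, 14 members were higher, and 9 were higher at all 3 replicate numbers. The constitutive chaperone Hspa8 (chromosome 9, 40800984 to 40810087) stood at 1761 ± 153 RPM in DMSO and 2547 ± 281 RPM in YH250, and the co-chaperone Stip1 at 90.6 ± 15.6 and 154 ± 13.3 RPM. The inducible and near-identical Hspa1b and Hspa1a had 3.35 ± 1.06 and 23.8 ± 22.1 RPM, and 2.75 ± 1.56 and 9.58 ± 3.78 RPM, both highest in YH250 2 (48.9 and 12.9 RPM). Without that library the list's median was 0.16 (camera adjusted p = 0.00124). Over all genes 0 members passed with limma (4 had an unadjusted p under 0.05), and adjusted over the list alone 0 passed without the block and 4 with it. The list was not called after quantile normalization (median 0.13, camera adjusted p = 0.072) or without YH250 3 (0.19, camera adjusted p = 0.0541).

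**Figure D2:**
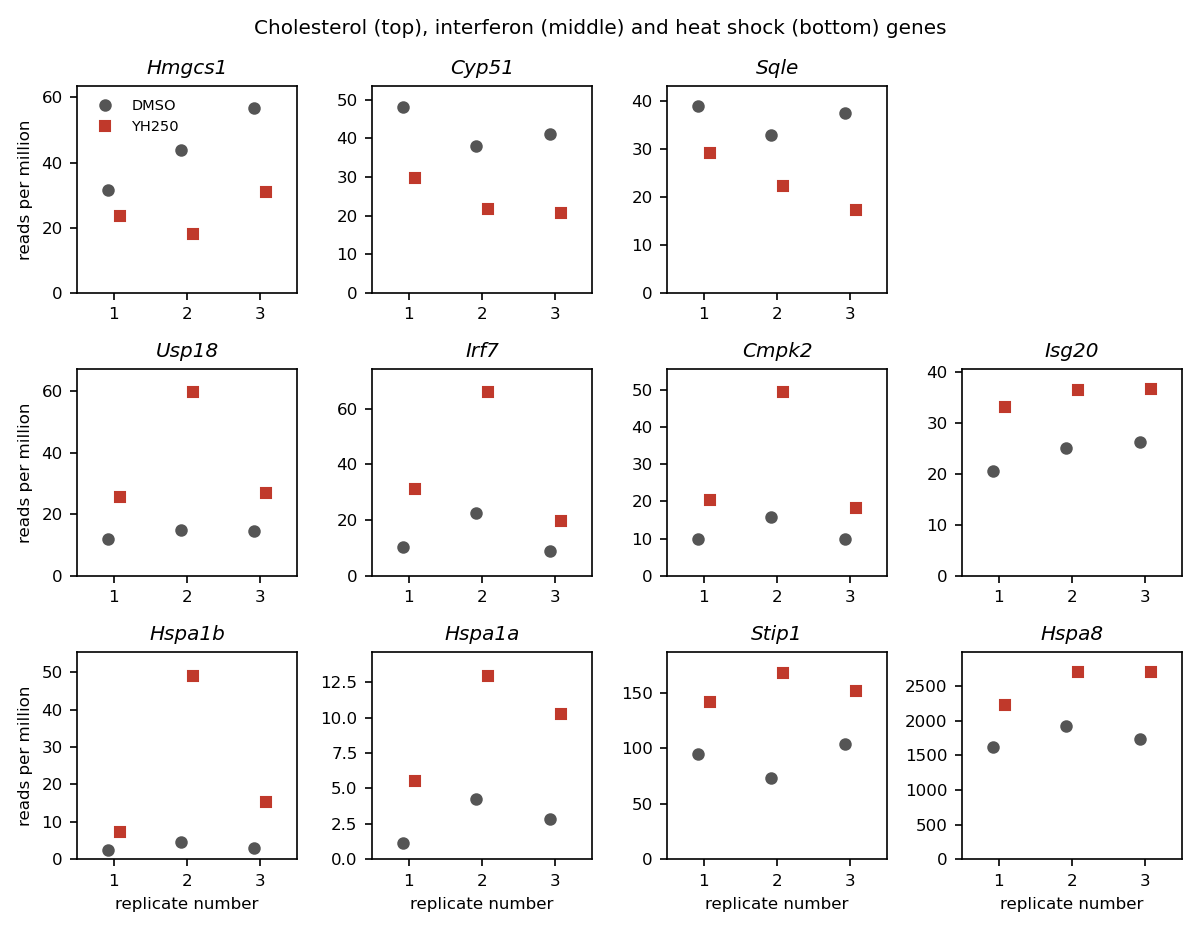
Expression in RPM (vertical axes, from 0) of 11 genes in each library by replicate number (horizontal axes), with DMSO as grey circles and YH250 as red squares, 1 point per library: cholesterol genes in the top row, interferon genes in the middle and heat shock genes at the bottom. Within each number the YH250 point of Hmgcs1, Cyp51 and Sqle is the lower one and that of the other 8 genes the higher one, although none passed the test over all genes. The genes were taken from their lists for a small unadjusted p in these libraries, which favours a shared sign.

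Cell cycle genes rose in YH250. The S-phase list had a median log2 fold change of 0.38, with 27 of 30 members higher in mean and 18 higher at all 3 numbers (camera adjusted p = 2.5e-05; adjusted p = 0.775 with an estimated correlation). The G2/M list had a median of 0.42, with 24 of 30 members higher in mean and 13 higher at all numbers (camera adjusted p = 0.00052; adjusted p = 0.775 with an estimated correlation). The helicase subunit Mcm5 had 70.9 ± 11.9 RPM in DMSO and 106 ± 5.71 RPM in YH250, and the licensing factor Cdt1 had 42.8 ± 5.05 and 59.2 ± 4.48 RPM. The mitotic kinases Aurka and Aurkb had 15.2 ± 6.45 and 29.8 ± 8.09 RPM, and 24.9 ± 6.42 and 46.3 ± 16.4 RPM, and the mitotic activator Cdc20 had 23.0 ± 5.03 and 37.0 ± 2.98 RPM. Adjusted over the list alone, 0 members of either list passed without the block, and 1 S-phase member passed with it. Neither list was called without DMSO 2 (medians of 0.24 and 0.04) or without YH250 3 (0.24 and 0.16), whereas without DMSO 3 the medians were 0.68 and 0.77. Both lists were also higher in the libraries numbered 3 than in those numbered 1 (medians of 0.63 and 0.81).

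Genes of stem cell identity fell as a group. The median log2 fold change over 48 members was -0.20, with 36 members lower in mean and 14 lower at all 3 numbers (camera adjusted p = 0.0175; adjusted p = 0.775 with an estimated correlation). The stem cell factor receptor Kit (chromosome 5, 75574916 to 75656722), also a sort marker, had 265 ± 52.6 RPM in DMSO and 169 ± 44.7 RPM in YH250, with log2 differences of -0.54, -0.72 and -0.71 at numbers 1, 2 and 3. Runx1, a transcription factor of blood stem cells, had 134 ± 33.7 and 97.8 ± 2.52 RPM, and the X-linked transcription factor Zfx had 86.5 ± 8.44 and 56.1 ± 23.4 RPM. Hlf, a transcription factor that marks stem cells, had 320 ± 160 and 248 ± 131 RPM, and Mecom 69.4 ± 43.9 and 57.1 ± 34.7 RPM. The same list was lower in the libraries numbered 3 than in those numbered 1 (median -1.24). No member passed adjusted over the list alone with or without the block. The list was not called with array weights (median -0.16), without DMSO 1 (-0.08), without DMSO 2 (-0.15) or without both libraries numbered 3 (-0.11), and without YH250 3 its median turned to 0.11 (camera adjusted p = 0.667), whereas it was -0.58 without DMSO 3 and -0.49 without YH250 1.

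The transcripts of oxidative phosphorylation rose as a group over the 3 against 3 libraries, and so did those of cytosolic ribosomal proteins, whose median turned to -0.03 after quantile normalization; at number 3 both medians were below 0. The oxidative phosphorylation list had a median log2 fold change of 0.19 over 74 members, of which 68 were higher in mean and 15 at all 3 numbers (camera adjusted p = 0.000117; adjusted p = 0.775 with an estimated correlation). Its medians were 0.44, 0.38 and -0.22 at numbers 1, 2 and 3. It was still called, with smaller medians, after quantile normalization (0.108) and without both libraries numbered 2 (0.106). Examples were Cyc1 (76.3 ± 3.28 RPM in DMSO and 127 ± 12.05 RPM in YH250), Ndufv1 (65.7 ± 4.92 and 101 ± 18.4 RPM), Ndufa9 (82.4 ± 7.32 and 131 ± 29.4 RPM) and Uqcrc1 (235 ± 62.1 and 360 ± 86.3 RPM). The ribosomal protein list had a median of 0.14 over 78 members, 76 of them higher in mean and 7 at all 3 numbers (camera adjusted p = 0.00207; adjusted p = 0.775 with an estimated correlation), with medians of 0.33, 0.29 and -0.23 at numbers 1, 2 and 3. Rpl3 had 2410 ± 366 and 3048 ± 424 RPM. No member of either list passed adjusted over the list alone with or without the block. Neither list was called without DMSO 1 (medians of 0.03 and 0.03), without DMSO 2 (0.07 and 0.07) or without both libraries numbered 1 (0.06 and 0.03), nor was the former without YH250 3 (0.11), or the latter without both libraries numbered 2 (0.05) or after a correction for transcript length and GC content (0.06). In the other direction, the medians were 0.45 and 0.28 without DMSO 3 and 0.40 and 0.31 without both libraries numbered 3.

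Markers of T and NK cells rose as a group, at low levels. The list had a median log2 fold change of 0.39 over 16 members, 13 of them higher in mean and 3 higher at all 3 numbers (camera adjusted p = 0.0171; adjusted p = 0.775 with an estimated correlation). The T cell receptor subunits Cd3e and Cd3d had 3.29 ± 5.27 and 10.7 ± 4.08 RPM, and 7.71 ± 11.4 and 15.2 ± 5.99 RPM, in DMSO and YH250. Il2rb, a cytokine receptor subunit, had 2.71 ± 3.42 and 12.02 ± 7.91 RPM. The same list was higher in the libraries numbered 3 than in those numbered 1 (median 1.74), and 3 members passed adjusted over the list alone with the block against 0 without it. It was not called with no minimum mean (median 0.39, camera adjusted p = 0.0671), without DMSO 1 (0.11), without DMSO 2 (0.31), without YH250 3 (0.19) or without both libraries numbered 1 (0.35). Where it was called, its median lay between 0.23 (pseudocount of 5) and 1.19 (minimum mean of 5), with 1.02 without DMSO 3.

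The lists closest to the stated target of the compound did not pass. Wnt and catenin target genes had a median log2 fold change of -0.04 over 16 tested members (camera adjusted p = 0.518) and pathway components -0.06 over 27 (camera adjusted p = 0.622). Axin2, a direct target of the pathway, was below the minimum for testing, at 0.611 ± 0.933 RPM in DMSO and 0.651 ± 0.992 RPM in YH250. Myc had 238 ± 53.5 and 190 ± 27.4 RPM, Ccnd1 19.8 ± 6.64 and 22.1 ± 5.25 RPM, and Birc5, which encodes survivin, 60.2 ± 38.5 and 67.0 ± 36.1 RPM. The catenin gene Ctnnb1 had 147 ± 45.6 and 145 ± 2.68 RPM. The coactivator genes Ep300 and Crebbp had 62.5 ± 13.3 and 52.5 ± 20.9 RPM, and 122 ± 18.8 and 120 ± 28.7 RPM. Genes of division mode and polarity had a median of -0.10 over 21 members (camera adjusted p = 0.315). Numb, a cell fate determinant inherited unequally at some divisions, had 6.99 ± 2.02 and 9.34 ± 3.34 RPM, the RNA-binding regulator Msi2 246 ± 5.49 and 181 ± 35.7 RPM, and the polarity kinase Prkci 20.7 ± 8.64 and 9.81 ± 2.197 RPM. The list of quiescence genes had a median of -0.02 (camera adjusted p = 0.78), with Cdkn1a at 35.0 ± 6.02 and 34.0 ± 5.33 RPM and Cdkn1c at 27.0 ± 25.9 and 25.3 ± 20.3 RPM. These p-values do not show that the genes stayed equal, given the spread between numbers.

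In all, 9 of the 32 lists passed, 7 higher and 2 lower in YH250, and none passed with an estimated correlation or with limma's fry test (smallest adjusted p = 0.257). With the replicate number as a block, 14 lists passed under the preset correlation and again none with an estimated one (smallest adjusted p = 0.631). The block kept all 9 and added glycolysis and hypoxia (median 0.20, adjusted p = 0.046 with the block) and 4 marker lists of other cells. These 4 were B cell (0.63, adjusted p = 0.00037), endothelial and stromal cell (0.38, adjusted p = 0.046), mast cell, basophil and eosinophil (1.65 over 5 members, adjusted p = 0.0153) and multipotent and lymphoid-primed progenitor (0.19, adjusted p = 0.0445). Glycolysis and hypoxia was not called with the block after the correction for transcript length and GC content (median 0.13, adjusted p = 0.181), and its median was 0.37 without YH250 3, 0.12 without YH250 1, 0.12 without YH250 2 and 0.12 without DMSO 3. The mast cell list's median was 0.25 with no minimum mean, 0.80 with a pseudocount of 5, 0.95 without DMSO 1 and 0.82 without DMSO 2, and under 5 of its members were tested with a minimum mean of 5 or without YH250 3. Its medians at numbers 1, 2 and 3 were only 0.43, 0.004 and 0.68. Its member Prss34 was at 30.4 RPM in YH250 3 and at 0.0321 RPM or less in every other library. Without DMSO 1 the B cell and progenitor medians turned to -0.41 and -0.51, and without YH250 2 the endothelial one to -0.09. Among their members, Cd79b had 107 ± 58.3 and 176 ± 120 RPM, and Mpo 63.2 ± 97.2 and 96.3 ± 111 RPM. Adjusted over the list alone, 2 B cell and 2 mast cell members passed with the block and 0 without it. The other lists did not pass in either fit, with camera adjusted p-values from 0.0905 to 0.913 without the block. Their median log2 fold changes were 0.28 for monocytes and macrophages, 0.19 for the unfolded protein response, 0.19 for Notch targets, 0.14 for ribosome biogenesis and -0.01 for inflammation, which camera placed higher. They were -0.01 for neutrophils and granulocyte progenitors (mean 0.07, placed lower by camera), -0.02 for DNA methylation and Polycomb, -0.03 for p53 targets, -0.04 for immediate early genes, -0.06 for acetyltransferases and deacetylases, -0.10 for TGF-beta and BMP targets, -0.28 for megakaryocytes and -0.28 for erythroid cells. The 5 sort marker genes had a median of 0.27 while camera placed the list lower without the block (adjusted p = 0.913) and higher with it (adjusted p = 0.571). Adjusted over the list alone, 2 of the 5 passed with the block, Kit lower and Ly6a higher in YH250, and 0 without it. Of them, Ly6a, which encodes Sca1, had 159 ± 80.0 and 216 ± 99.1 RPM, and Itga2b, which encodes CD41, 21.6 ± 19.8 and 23.6 ± 15.3 RPM.

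**Figure D3:**
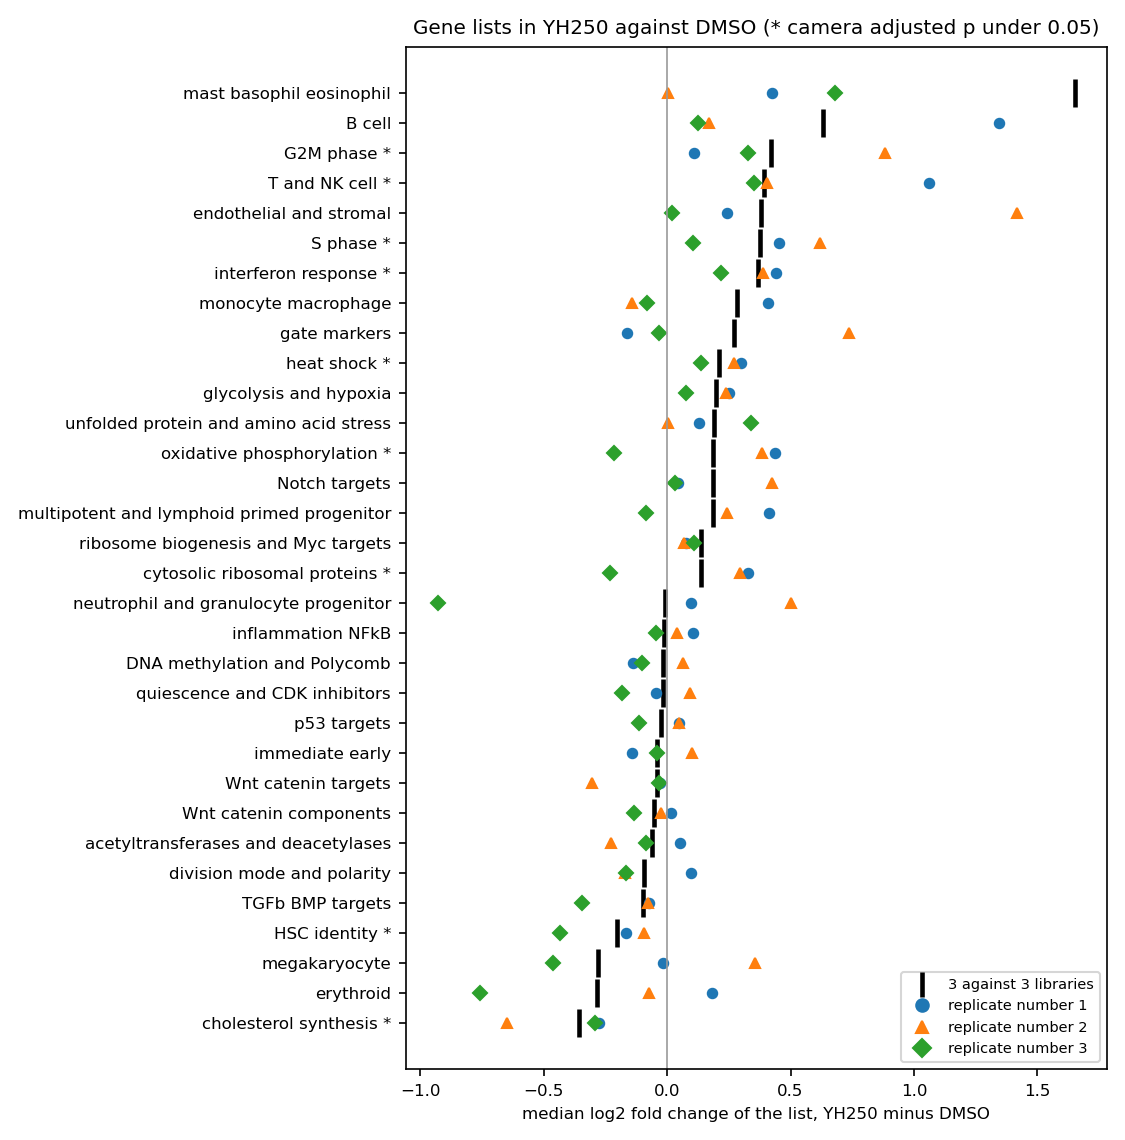
Median log2 fold change, YH250 minus DMSO (horizontal axis), of the tested members of each of 32 gene lists (vertical axis): black bars give the 3 against 3 libraries, blue circles, orange triangles and green diamonds the single comparisons at replicate numbers 1, 2 and 3, and an asterisk marks the 9 lists with a camera adjusted p under 0.05. Among the 9 marked lists, only the oxidative phosphorylation and ribosomal protein medians change sign between numbers. Both lie below 0 at number 3 alone, the latter also over all libraries after quantile normalization (-0.03).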

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

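The removal of both libraries of a number, the length and GC correction, and the estimated correlation and fry under the block were chosen after the data had been seen. The count of 0 changed genes (limma) was the same under all alternatives run, including an adjusted p threshold of 0.1, with 99 to 1012 genes at an unadjusted p under 0.05. The 9 lists became 14 with the replicate block, which added 5 and kept all 9; adjusted over the list alone, 0 members passed without the block in any list, and 1 to 4 passed with it in 8 lists. They became 0 with an estimated inter-gene correlation, 0 with fry, and 0 with either of these under the block, so the calls rest on camera in its preset form. Without the block the estimated correlation was -0.015 for heat shock, 0.020 for interferon and 0.059 for cholesterol synthesis. In the other called lists it ran from 0.33 (HSC identity) to 0.73 (ribosomal proteins). The heat shock estimate was below the preset of 0.01, so a higher correlation did not remove that call. Other settings with all libraries gave 7 to 12 lists. Leaving out each library in turn gave 3 to 13, with 3 without DMSO 2 and 5 without YH250 3, and each removal leaves the numbers unequal between treatments. The interferon and cholesterol lists were called in each of these. Planned count models were not run, since whole reads were not recovered.

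The ribosomal protein list turned to -0.0345 under quantile normalization, and the progenitor list to -0.1029 under array weights. Over single left-out libraries, medians of lists that turned ranged from -0.4099 to 1.555 (B cell), -0.5762 to 0.1104 (HSC identity), -0.09228 to 0.8058 (endothelial and stromal) and -0.5104 to 1.124 (progenitor). No named gene passed in any setting, and log2 differences of these changed sign over single left-out libraries: Birc5 -0.2466 to 0.7143, Ccnd1 -0.03007 to 0.4125, Ccr9 -0.05724 to 2.276, Cd48 -0.5558 to 1.709, Cdkn1a -0.1584 to 0.09209, Cdkn1c -0.934 to 0.8312, Crebbp -0.2147 to 0.1156, Ctnnb1 -0.1521 to 0.2574, Ep300 -0.5589 to 0.05275, F2r -1.024 to 0.007766, Hlf -0.8539 to 0.1016, Itga2b -0.4049 to 0.97, Lepr -0.1163 to 2.328, Mecom -0.7893 to 0.2668, Pf4 -1.441 to 0.08513 and Slamf1 -0.9587 to 1.336. Without both libraries numbered 2, values turned for the endothelial list (-0.03604), Birc5 (-0.04039), Ccnd1 (-0.1923), Crebbp (0.05319), Ctnnb1 (-0.1639), Ep300 (0.07202), Lepr (-0.3633) and Slamf1 (-0.6629), without both numbered 1 for Ctnnb1 (-0.04781), and without both numbered 3 for Cdkn1c (0.2583). Array weights turned Cdkn1a (0.02636), Crebbp (0.04723) and F2r (0.1006), and a pseudocount of 5 turned Slamf1 (-0.00666). Ctnnb1 was -0.006174 with TMM, -0.04413 with quantile normalization and -0.05843 with the length and GC correction, with or without the replicate block. Apart from the removals, which leave fewer libraries, the cause was not tested. Depth limits mainly genes near 1 RPM, which rest on 21.96 to 31.19 reads.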

Other observations

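The test of cell stages behind the replicate numbers, the contrasts between numbers, the length and GC correction and the axis shares with both libraries of a number left out were chosen after the data had been seen. Genes of early blood differentiation separated the libraries by replicate number. Of 16 multipotent and lymphoid-primed progenitor genes, 14 were higher in the libraries numbered 3 than in those numbered 1 at a limma adjusted p under 0.05, as were 15 of 16 B lineage genes. Dntt, the DNA polymerase of early lymphoid cells, was at 5.76 and 10.2 RPM in number 1 (DMSO and YH250) and at 633 and 614 RPM in number 3. Il7r, the interleukin-7 receptor, was at 1.01 and 6.33 RPM against 122 and 130 RPM. Ighm, the immunoglobulin mu chain, was at 59.1 and 368 RPM against 6491 and 15344 RPM. In the other direction, 24 of 48 stem cell identity genes and 5 of 17 megakaryocyte genes were lower in number 3. Esam was at 105 and 79.1 RPM in number 1 and 8.79 and 6.67 RPM in number 3. Number 2 minus number 1 had medians of 2.03 (progenitor), 1.72 (B cell), -0.97 (megakaryocyte) and -0.32 (HSC identity). Their camera adjusted p-values were 9.6e-14, 1.6e-06, 0.00013 and 0.0022, and 0.861 for each with an estimated correlation.

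Libraries that share a replicate number resembled each other across treatments, and a candidate explanation is that the numbers stand for different stages of stem and progenitor cells: number 3 minus number 1 had a median log2 difference of 3.67 in the progenitor list and -1.24 in the HSC identity list (camera adjusted p = 1.7e-13 and 5.7e-12; adjusted p = 0.503 for both with an estimated correlation). Counting noise is argued against, since the lowest same-number correlation was 0.544 among 3245 genes with a mean of at least 50 RPM. Mature neutrophils or red cells in the number 3 sorts are argued against too, since 9 of their most abundant transcripts stayed at or below 66.9 RPM there, and the sort excludes lineage-positive cells. With each library's trend on transcript length and GC removed, the progenitor median was 3.46 and the HSC identity median -1.23, so that trend does not account for the difference. The removal moved a gene by a median of only 0.18 on the log2 scale, so it cannot decide on library preparation as a source in other ways. The share of reads in genes also differed by number, at 70.0% and 77.9% in number 1 (DMSO and YH250) and 95.9% and 93.6% in number 3. What would have made the cells differ by number stays open and untested, whether through the mice, the sort gate or the sort day, and the labels give no day.

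For the rise of oxidative phosphorylation and ribosomal protein transcripts, a trend on transcript length and GC content, removed library by library with the replicate block kept, took the oxidative phosphorylation median from 0.187 to 0.126 and the ribosomal protein median from 0.136 to 0.0565, so it may account for most of the latter but not for the former as a whole. After the correction the ribosomal list was no longer called. Its camera adjusted p was 0.00812 before and 0.244 after with the block, and 0.00207 before and 0.22 after without it (SD over members 0.07 before). TMM scaling left medians of 0.161 and 0.11, but it moved the median of all genes only from a log2 fold change of 0.02 to -0.01, so it tests the scaling alone and not the share of reads in genes as a source. That share was 70.0% in DMSO and 77.9% in YH250 at number 1, 75.6% and 84.9% at number 2, and 95.9% and 93.6% at number 3, and the list medians were above 0 at numbers 1 and 2 and below 0 at number 3, so this source stays open. An effect of treatment that depends on the number also stays open and was not tested.

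The fall of stem cell identity genes and the rise of cell cycle genes follow the direction from number 1 to number 3, so YH250 libraries shifted along that axis are a candidate explanation. Over the genes called between numbers 3 and 1, the treatment effect had a slope of 0.077 on the axis, and slope times axis, with the list's own genes left out of the slope, gave 45.8% of the identity list's median (95% bootstrap interval over genes 21.9% to 78.7%), which leaves the shift open for that list. It gave 12.9% for S phase, 14.8% for G2/M, -1.14% for the interferon list and 5.87% for the cholesterol list, with upper limits of 17.6%, 42.5%, 5% and 18.8%, which argues against the shift as their main source. With both libraries of a number left out in turn and the slope fitted again, the highest shares were 21.9% for S phase and 30.3% for G2/M, without number 2, and 81.45% for the identity list, without number 3. Genes are not independent, so these intervals are too narrow, which leaves the reading least secure for G2/M, with its upper limit of 42.5%. A shift along another axis, or an effect of YH250 itself, stays open.

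The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 splits gave at least the 0 genes of the real one, and the highest other gave 4. That split put DMSO 1, DMSO 2 and YH250 1 against the rest and gave 2049 genes at an unadjusted p under 0.05, which points to the structure by replicate number. For lists, 4 of the 10 splits gave as many as the 9 of the real one, and the highest other gave 13. Among the 4 splits that part all 3 pairs, the real one gave the most lists, 9 against 5, 1 and 0 without the block and 14 against 7, 2 and 0 with it, and the most genes at an unadjusted p under 0.05 with the block, 1012 against 544, 416 and 380. With only 4 such splits, the first rank cannot tell an effect of treatment from chance.

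The nuclear noncoding RNA Neat1 was lower in YH250 at each number, with 93.6 ± 26.6 RPM in DMSO and 52.3 ± 15.2 RPM in YH250 (SD, n = 3 each), as were Xist and Kcnq1ot1, whereas Malat1, with 7602 ± 655 and 6405 ± 1376 RPM, was lower at numbers 1 and 2 only; Neat1 and Malat1 were chosen after their values were seen.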
